A study of Salmo salar with 9 samples.

How the data were processed

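RNA sequencing libraries were made from gill filament tissue of Atlantic salmon (Salmo salar). Per the labels, 3 libraries came from healthy fish (Control), 3 from damaged filament tissue of fish with complex gill disease (CGDdt) and 3 from undamaged filament tissue of such fish (CGDndt). Complex gill disease is a gill condition of farmed salmon in the sea that is linked to several agents at the same time. Per the labels' protocols, RNA was extracted with Trisure and 1 µg of total RNA entered a TruSeq Stranded Total RNA library preparation. Per the submitters' processing notes, bcl2fastq 2.20, FastQC and DESeq2 were used. The aligner, the counting program, its strand setting, the annotation and the genome build are not given in the sources used here, so no coordinates are reported.

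The deposited values were raw counts per gene, in a table of 13232 rows named by gene symbol, with 1 column for each of the 9 libraries and no row for genes without a symbol. The column names call each library a pool and number the pools from 1 to 3 within a group. Columns whose names end in CGD, Non-CGD and Control were read as CGDdt, CGDndt and Control. The names match no single sample title, so a pool number names a column and not a known fish. Of the CGDndt samples 2 of 3 have titles of the name series BKD. The other CGDndt sample and all CGDdt samples are of the series IG, and all Control samples of the series CG. What these series stand for is not given in the sources used here. Both comparisons with Control are wholly confounded with the series, and CGDdt against CGDndt partly. Neither the labels nor the header say whether a pool held tissue of several fish, and p-values measure the spread between these libraries only. In the deposited table the counts of the Control columns were written with a decimal point and those of the other columns without, and 5 rows, with at most 4 counts in any other library, were blank in the Control columns. Those 5 rows were left out. Another 12 rows had names that a spreadsheet had turned into dates. They were kept in the fits and are not named. Between 78.8% and 90.2% of counts from 1 to 10 were even numbers in each library, against 52.0% to 59.5% of counts from 101 to 1000. Both mates of a pair may have been counted, which was not tested. Counting errors of low counts would then be wider than the intervals given.

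Total counts ranged from 5904785 to 7489998 per library, with a median of 6844371, and the 10 most abundant genes took 3.83% to 6.31% of them. Within groups the libraries differed by more than sampling noise, with a chi-square per degree of freedom of 15.1 to 38.9 between libraries, so none was treated as a repeat of another. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups as design, which left 11314 genes and removed 1913, and libraries were scaled by TMM. Each comparison used edgeR's robust quasi-likelihood F test, two-sided, in a fit of all 9 libraries with no covariates, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Values per library are TMM-scaled CPM, given as mean and SD over 3 libraries. Where a group held at most 10 counts of a gene named for its size of change, the ratio of group totals is given with its exact (Clopper-Pearson) 95% interval, and a group at 0 was set to a floor of 3 counts over the whole group. Intervals and floors cover counting error only.

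The gene lists, 24 in all with 452 tested genes, were written before the data were examined. They covered immune cells and mediators, tissue repair, epithelium, ionocytes, mucous cells, proliferation, stress, metabolism and markers of other cell types the filament can hold. A gene joined a list by its symbol, duplicate copies included, and false symbol matches were removed before any test. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 24 lists of a comparison. The same test with the correlation estimated per list was an alternative, under which 0 of the 24 lists passed in each of the 3 comparisons. Named genes were chosen by a rule fixed before the data were examined. For each comparison they were the 8 largest rises and the 8 largest falls past the threshold with a mean of at least 1 CPM and no overlap between both groups' libraries, and up to 4 members of each list with the lowest adjusted p. Uncharacterized genes and duplicate copies with the description of a gene already taken were to be skipped in the former part, but the table gave no descriptions, so only rows with date-like names were skipped. Salmon carry many duplicated genes, and reads of near-identical copies may be divided between the copies. By their symbols krt18a.1 and krt18b, postn and postnb or col11a1 and col11a1b may be such copies, but sequences were not compared.

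The procedure was tested on simulated counts with the levels, library sizes and spread of these data and 200 changed genes outside the lists. For CGDdt against Control, edgeR recovered 41.0% of simulated 2-fold and 80.8% of 4-fold changes among 11150 genes tested, and called 7 unchanged genes. For CGDndt against Control it recovered 42.4% and 83.8% among 11151 genes tested, with 7 unchanged genes called, and for CGDdt against CGDndt 46.9% and 91.0% among 11153, with 11. A shift of 0.5 on the log2 scale of the extracellular matrix list was recovered with an adjusted p of 2.13e-13, 2.14e-13 and 7.51e-12 in the 3 comparisons, and 0 other lists were called. Genes were simulated independently, so this does not test how camera treats correlated genes.

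Alternatives were other scalings (median of ratios, upper quartile), other filters on low counts, DESeq2 1.42.0, limma-voom with quality weights, fits of only the 6 libraries compared, each library left out in turn and camera with an estimated correlation. Chosen after seeing the data were fits without the rows 5nt1a and nnt, with the pool number as a replicate block and with a cartilage score (the mean log2 CPM of the tested cartilage markers) as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.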

Results

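Gene expression was measured by RNA sequencing in gill filaments of Atlantic salmon, with 3 libraries each from healthy fish (Control), from damaged filament tissue of fish with complex gill disease (CGDdt) and from undamaged filament tissue of such fish (CGDndt). Total counts were 5904785, 7139625 and 6262930 in the CGDdt libraries of pools 1 to 3, 7018920, 6844371 and 7277642 in the CGDndt libraries and 5920871, 6628114 and 7489998 in the Control libraries. On the first principal component of log2 CPM, which held 29.3% of the variance, the CGDdt libraries lay between -45.7 and -28.5 and the other 6 libraries between 8.1 and 32.0. CGDndt and Control libraries overlapped on it.

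The comparison of CGDdt with Control asked how damaged filament tissue of diseased fish differed from healthy filaments. Transcripts of matrix proteases and of a lymphocyte-attracting chemokine were higher in the damaged tissue. mmp9, a gelatinase of activated leukocytes, was 8.51-fold higher, at 1380 ± 173 CPM in CGDdt against 163 ± 87.1 CPM in Control (SD, n = 3, log2 fold change 3.09, SE 0.35, edgeR adjusted p = 0.00157). The collagenase mmp13 was 4.96-fold higher, at 228 ± 39.1 against 46 ± 7.18 CPM (log2 fold change 2.31, SE 0.21, adjusted p = 0.000135). ccl19, a chemokine that attracts lymphocytes and dendritic cells, was 4.06-fold higher, at 341 ± 64.1 against 83.8 ± 6.98 CPM (log2 fold change 2.02, SE 0.20, adjusted p = 0.000192). Lower in damaged tissue was sgpp2, a phosphatase of sphingosine 1-phosphate, by 4.06-fold, at 14.8 ± 4.32 against 59.8 ± 14 CPM (log2 fold change -2.02, SE 0.26, adjusted p = 0.00265). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 390 of 11314 genes changed, 239 higher and 151 lower. Of these, 167 higher and 78 lower genes changed at least 2-fold. The count was 111 without CGDdt pool 2, 67 without CGDdt pool 3, 593 without CGDndt pool 1, 76 without Control pool 2 and 50 without Control pool 3. Of the 390 genes, 36 (27 higher, 9 lower) passed in each of the 9 fits that left out a library. DESeq2 called 1073 genes, limma-voom 986 and a fit of the 6 libraries alone 728. All 390 passed in DESeq2 too, and 385 passed in limma-voom.

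The largest rises were in genes nearly silent in Control. lepb2, a leptin, had 680 counts over the CGDdt libraries and 1 over the Control libraries, a ratio of 729 (exact 95% interval 130 to 28800). mip2a had 595 and 4 counts, a ratio of 159 (61.9 to 587). mstnb, a myostatin, had 88 and 2 counts, a ratio of 47.1 (12.7 to 395), and 13b1 72 and 2 counts, a ratio of 38.6 (10.3 to 325). Among more abundant genes, asal was 35.1-fold, ecm1b (extracellular matrix protein 1) 23-fold and msc (the transcription factor musculin) 17.2-fold higher. Next to sgpp2, the largest falls were in gabrb2a, a GABA receptor subunit, with 2 against 54 counts, which is 25.2-fold lower (exact 95% interval 6.65 to 213), in mpz (myelin protein zero, 5.1-fold lower), rgs11 (5.09-fold), sal (4.43-fold), mical3b (4.11-fold) and tnk1 (3.87-fold). The rows 5nt1a and nnt also passed and are described with CGDndt. Of the 43 changed genes named for this comparison, 11 passed in all 9 fits that left out a library, among them lepb2, mip2a, sgpp2, ccl19, mmp9, mmp13, tgfbi, thbs1b and postn. The other 32 missed the threshold in at least 1 such fit, most often without Control pool 3 (29 genes, adjusted p of 0.050 to 0.209), CGDdt pool 3 (28 genes, 0.0559 to 0.184), Control pool 2 (28 genes, 0.0538 to 0.166) and CGDdt pool 2 (22 genes, 0.0617 to 0.154).

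In CGDdt against Control 9 of 24 lists passed in camera. Of the 10 ways to divide these 6 libraries into groups of 3, 4 called at least as many lists, the real one included. Genes of extracellular matrix and wound repair rose as a group in CGDdt. Of 43 tested members 13 were higher and 0 lower than in Control, or 28 higher and 2 lower adjusted over the list alone, with a median log2 fold change of 0.91. The camera test gave an adjusted p = 3.28e-11, and an adjusted p = 0.67 with an estimated correlation. postn (periostin) was 5.65-fold, tgfbi (a matrix protein induced by TGF-beta) 5.4-fold, thbs1b (a thrombospondin) 3.58-fold and fgf10a (a mesenchymal growth factor) 10.8-fold higher. Markers of cartilage, which forms the filament skeleton, moved the same way, with 6 of 17 members higher, 12 adjusted over the list alone, and all 17 above 0 (median 1.61, camera adjusted p = 2.22e-08, adjusted p = 0.67 with an estimated correlation). col11a1 was 5.44-fold, col10a1b 3.39-fold and acanb (aggrecan) 2.54-fold higher. The mean log2 CPM of the cartilage markers lay 1.13 to 2.41 above the Control mean in the CGDdt libraries, where the Control libraries themselves ranged from -0.84 to 0.77. With this cartilage score as a covariate, 27 genes changed and the matrix list gave a camera adjusted p = 2.03e-12. Since the scores of both groups did not overlap, that fit cannot separate cartilage from the group.

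Immune lists were mixed in CGDdt. Of 17 inflammatory cytokines and chemokines 2 were higher, ccl19 and il11a (4.61-fold), or 3 higher and 2 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.582). Among 14 phagocyte and granulocyte markers mmp9 and mmp13 were the 2 that rose, also adjusted over the list alone (camera adjusted p = 0.0544). Of 6 acute phase and antimicrobial genes 1 rose, the complement component c7a (6.30-fold, also adjusted over the list alone, list adjusted p = 0.746). Interferon-stimulated genes fell as a group, with 27 of 28 log2 fold changes below 0 and a median of -0.31 (camera adjusted p = 0.00386, adjusted p = 0.84 with an estimated correlation). ifit9 was the 1 member that passed, 2.21-fold lower, and 2 members were lower adjusted over the list alone. T cell markers (median 0.12, adjusted p = 0.750), B cell and immunoglobulin markers (median 0.04, adjusted p = 0.931) and antigen presentation genes (median -0.12, adjusted p = 0.746) did not pass in camera. Adjusted over the list alone, 1 B cell marker and 1 antigen presentation gene were higher.

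Among epithelial genes, keratins and a junction gene changed in opposite directions in CGDdt filaments. krt8 was 2.23-fold, krt18a.1 1.97-fold and krt18b 1.89-fold higher. oclnb (occludin, a tight junction protein) was 2.05-fold lower, at 165 ± 41.6 against 338 ± 50.9 CPM. The list of 31 epithelial genes had 3 higher and 1 lower members, 5 and 2 adjusted over the list alone, and did not pass (camera adjusted p = 0.746). Ionocyte genes, which serve salt transport, were lower as a group, with 18 of 21 below 0 and a median of -0.46 (camera adjusted p = 0.0108, adjusted p = 0.67 with an estimated correlation). Singly 0 members passed, also adjusted over the list alone. Of the 21 members 2, slc4a1a and slc4a1b, also stood in the erythroid list, which was lower too (11 of 12 below 0, median -0.67). The sodium chloride cotransporter slc12a3 was at 12.8 ± 3.74 CPM in CGDdt and 31.6 ± 14.2 CPM in Control (edgeR adjusted p = 0.0667). Mucous cell genes (median -0.30, camera adjusted p = 0.529) did not pass.

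Hypoxia and glycolysis genes had 7 of 35 members higher and 1 lower in CGDdt, 10 and 2 adjusted over the list alone. The glycolytic enzyme pgk1 was 1.90-fold and hif1aa, a hypoxia-inducible factor, 1.78-fold higher, while its relative epas1 was 2.31-fold lower. The list passed (camera adjusted p = 0.0398, adjusted p = 0.84 with an estimated correlation), but not without CGDdt pool 1 (0.148), pool 2 (0.104) or pool 3 (0.167), CGDndt pool 1 (0.0689) or pool 2 (0.0968), or Control pool 2 (0.127) or pool 3 (0.224). Cell cycle genes rose as a group. mcm5, part of the replicative helicase, was 2.00-fold higher as the 1 member of 21 to pass, and 7 members were higher adjusted over the list alone (camera adjusted p = 0.00164, adjusted p = 0.84 with an estimated correlation, 0.0662 without CGDdt pool 3). Heat shock and unfolded protein response genes did so too. pdia4, a protein-folding enzyme, was 2.40-fold higher as 1 of 25, and 9 members were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0225, adjusted p = 0.84 with an estimated correlation, 0.140 without CGDdt pool 3 and 0.114 without Control pool 3). Of 46 cytosolic ribosomal proteins rpl15 alone passed, 1.62-fold higher, and 0 adjusted over the list alone, with a list median of 0.22 (camera adjusted p = 0.00792, adjusted p = 0.86 with an estimated correlation, 0.148 without CGDdt pool 1 and 0.0988 without Control pool 3). Erythroid markers were lower as a group with 0 of 12 members passing, also adjusted over the list alone (median -0.67, camera adjusted p = 0.0398, adjusted p = 0.86 with an estimated correlation, 0.325 without CGDdt pool 3, 0.0556 without CGDndt pool 3 and 0.502 without Control pool 1).

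The remaining lists did not pass in CGDdt against Control. Endothelial and pillar cell markers had a median of 0.32 (camera adjusted p = 0.0528), with the VEGF receptor kdrl 2.40-fold higher as 1 of 21. Thrombocyte markers had a median of -0.23 and a mean of 0.55 (adjusted p = 0.822), with the coagulation factor f5 10.9-fold higher as 1 of 4. For neuronal and neuroepithelial markers, where mpz was the 1 of 10 that passed, the camera adjusted p was 0.931. It was 0.185 for skeletal muscle markers (median -1.24), 0.287 for antioxidant and xenobiotic genes, 0.822 for apoptosis genes and 0.353 for oxidative phosphorylation. Adjusted over the list alone, kdrl, f5 and mpz were the members past in their lists, and 1 antioxidant gene was lower.

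**Figure D1:**
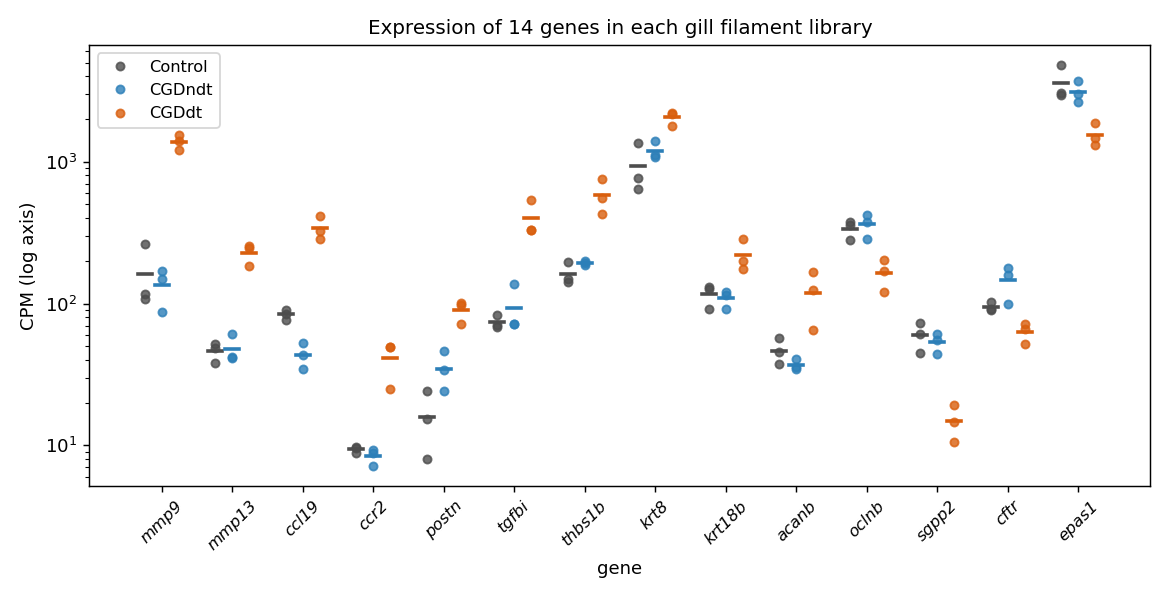
CPM of 14 genes (log axis) in each of the 9 gill filament libraries, with a point for each library and a bar for the mean of the 3 libraries of Control, CGDndt or CGDdt. mmp9 averaged 1380 CPM in CGDdt, 136 CPM in CGDndt and 163 CPM in Control, and sgpp2 averaged 14.8, 53.5 and 59.8 CPM.

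The comparison of CGDndt with Control asked whether filament tissue of diseased fish without visible damage differed from that of healthy fish. In edgeR's quasi-likelihood test 2 genes changed, 5nt1a and nnt, and the next lowest adjusted p was 0.532. 5nt1a had 938 to 1255 counts in each of the 6 libraries of diseased fish and 0 in each Control library, which puts it at least 982-fold higher in CGDndt and at least 1310-fold higher in CGDdt. nnt had 961 to 1278 counts in the Control libraries and at most 2 in the others. With CGDndt, which held 0 counts, set to the floor, nnt was 1220-fold lower there (exact 95% lower limit 991). In CGDdt it was 806-fold lower (exact 95% interval 314 to 2960). The sum of both rows lay between 123 and 208 CPM in all 9 libraries and did not change (log2 fold change -0.22, SE 0.18, edgeR adjusted p = 0.796 in CGDndt against Control). Over all rows 851 genes had an unadjusted p under 0.05, where 566 would by chance among 11314 independent tests. The CGDndt and Control libraries were also divided into mixed groups. With CGDndt pool 1 and Control pools 2 and 3 as a group, 1352 genes had such a p, and the other mixed splits gave 269 to 694. The count of the real split was thus not the highest. Without the rows 5nt1a and nnt 0 of 11329 genes changed in edgeR, and 846 had an unadjusted p under 0.05. With all rows limma-voom called 2 genes and DESeq2 15, and edgeR called 4 without CGDndt pool 1.

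Single genes of undamaged tissue that ranked highest in their lists are given as values, since none passed. ccl19 was at 43.6 ± 9.18 CPM in CGDndt and 83.8 ± 6.98 CPM in Control (SD, n = 3, edgeR adjusted p = 0.532). cd28, a costimulatory receptor of T cells, was at 11.8 ± 3.25 and 36.2 ± 13.7 CPM (adjusted p = 0.532). postn was at 34.7 ± 11.1 and 15.9 ± 8.10 CPM (adjusted p = 0.570) and il11a at 14.6 ± 6.27 and 3.98 ± 0.927 CPM (adjusted p = 0.567). The list tests called 4 groups, each with 0 members past the threshold. Of the 10 ways to divide these 6 libraries into groups of 3, 8 called at least as many lists, the real one included. Matrix and wound repair genes were higher (37 of 43 above 0, median 0.36, camera adjusted p = 9.4e-05), with scores of -0.13, 0.60 and 0.56 relative to the Control mean in pools 1 to 3. Skeletal muscle markers moved with them in the CGDndt libraries, at -1.23, 1.81 and 1.08, and did not pass (median 1.04, adjusted p = 0.202). Elsewhere both scores did not move together. In Control pools 1 to 3 the matrix scores were 0.19, -0.12 and -0.07 and the muscle scores -0.53, -0.52 and 1.06. In CGDdt they were 0.80 to 1.11 and -1.36 to -0.38. T cell markers (13 of 16 below 0, median -0.31, adjusted p = 0.00727), phagocyte and granulocyte markers (13 of 14 below 0, median -0.31, adjusted p = 0.00955) and ribosomal proteins (31 of 46 below 0, median -0.22, adjusted p = 2.72e-05) were lower. Each of the 4 lists called, the matrix list included, had a camera adjusted p = 0.81 with an estimated correlation. Adjusted over the list alone, 2 T cell markers and 8 ribosomal proteins were lower and 0 members of the matrix and phagocyte lists changed. Without CGDndt pool 2 the matrix, T cell and phagocyte lists each had an adjusted p of 0.108. The phagocyte list also missed without CGDndt pool 3 (0.0583) or Control pool 2 (0.0633). Without CGDndt pool 1 or without Control pool 3, 7 lists passed. The other 20 lists had camera adjusted p-values from 0.116 for cytokines and chemokines (median -0.42) to 0.963 for ionocyte genes (median 0.03) in CGDndt against Control. Interferon-stimulated genes (0.465) and cartilage markers (0.233, median -0.01) were among them. In these lists, adjusted over the list alone, 1 cytokine or chemokine was higher and 1 lower. Likewise 1 antigen presentation gene and 1 endothelial or pillar cell marker were lower.

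The comparison of CGDdt with CGDndt asked what set damaged filament tissue apart from undamaged tissue of diseased fish. Since 2 of 3 CGDndt samples carry the title series BKD, tissue damage and series are partly confounded in it. The chemokine ccl19 and the proteases mmp9 and mmp13 were higher in the damaged tissue. ccl19 was 7.80-fold higher (log2 fold change 2.96, SE 0.20, edgeR adjusted p = 1.34e-05), mmp9 10.2-fold (log2 fold change 3.35, SE 0.36, adjusted p = 0.00146) and mmp13 4.74-fold (log2 fold change 2.24, SE 0.21, adjusted p = 0.000246). Lower was cftr, the chloride channel of ionocytes, by 2.30-fold, at 63.2 ± 10 CPM in CGDdt and 145 ± 41 CPM in CGDndt (SD, n = 3, log2 fold change -1.20, SE 0.22, adjusted p = 0.0143). In edgeR's quasi-likelihood test 352 genes changed, 200 higher and 152 lower. Of these, 137 higher and 78 lower genes changed at least 2-fold. The balance of directions was not stable, with 177 higher and 167 lower genes under median-of-ratios scaling, 191 and 180 without a filter, 448 and 484 in DESeq2 and 112 and 127 without CGDndt pool 3. The count was 66 without CGDdt pool 2, 90 without CGDdt pool 3, 172 without CGDndt pool 1 and 192 without Control pool 3. Of the 352 genes, 48 (35 higher, 13 lower) passed in each of the 9 fits that left out a library. Of the genes named above, ccl19, mmp9 and mmp13 were among these 48, and cftr was not. DESeq2 called 932 genes, limma-voom 190 and a fit of the 6 libraries alone 132. All 352 passed in DESeq2 too, and 182 passed in limma-voom.

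Here too the largest rises were in lepb2, with 680 against 8 counts (a ratio of 96.5, exact 95% interval 48.7 to 224), mip2a (29.8-fold), asal (23.7-fold) and ecm1b (22.9-fold). They were followed by col9a2, a cartilage collagen (14.8-fold), tfpi2, a protease inhibitor (14.7-fold), and ca9, a carbonic anhydrase induced by low oxygen (13.4-fold). The largest falls were in hapln3, a hyaluronan link protein, with 4 against 92 counts, which is 20.3-fold lower (exact 95% interval 7.65 to 75.9), and in grem1, a BMP antagonist (8.51-fold lower). sema5b was 5.09-fold, col14a1a 4.53-fold, ccdc85ca 3.75-fold, sgpp2 3.63-fold, npnta 3.58-fold and atp1a2a 3.57-fold lower. Of the 47 changed genes named for this comparison 14 passed in all 9 fits that left out a library, among them lepb2, mip2a, tfpi2, mmp9, grem1, sgpp2 and ccl19. The other 33 missed in at least 1 such fit, most often without CGDdt pool 2 (27 genes, edgeR adjusted p of 0.0582 to 0.189), CGDdt pool 3 (26 genes, 0.0511 to 0.149) and CGDndt pool 1 (25 genes, 0.0537 to 0.120).

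Phagocyte markers rose as a group in damaged against undamaged tissue. All 14 phagocyte and granulocyte markers lay above 0, and mmp9 and mmp13 were among those past the threshold. Adjusted over the list alone 4 were higher (median 0.71, camera adjusted p = 5.11e-05, adjusted p = 0.63 with an estimated correlation). Of 16 T cell markers 2 were higher, the signalling adaptor sh2d1ab (3.15-fold) and cd28 (2.51-fold), or 2 higher and 1 lower adjusted over the list alone (median 0.41, camera adjusted p = 0.0121, adjusted p = 0.63 with an estimated correlation, 0.102 without CGDndt pool 2). cd22, a coreceptor of B cells, was 3.04-fold higher as 1 of 5 B cell markers (list adjusted p = 0.781). ifi30, a lysosomal reductase of antigen processing, was 2.51-fold higher as 1 of 6 antigen presentation genes (0.623). Interferon-stimulated genes were lower as a group with 0 of 28 members passing, also adjusted over the list alone (25 below 0, median -0.35, camera adjusted p = 0.0121, adjusted p = 0.63 with an estimated correlation, 0.0692 without CGDdt pool 3 and 0.599 without CGDndt pool 3). Among cytokines and chemokines ccl19 was higher and ptgs2b, a prostaglandin synthase, 1.87-fold lower (list adjusted p = 0.0673).

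Matrix and cartilage genes were again higher. Of 43 matrix and wound repair genes 8 were higher and 0 lower, 13 adjusted over the list alone (median 0.52, camera adjusted p = 1.08e-05, adjusted p = 0.63 with an estimated correlation). tgfbi was 4.27-fold, timp2 (a protease inhibitor) 4.25-fold, thbs1b 3.01-fold and pdgfra (a PDGF receptor of fibroblasts) 1.90-fold higher. Of 17 cartilage markers 5 were higher, 12 adjusted over the list alone (median 1.66, camera adjusted p = 2.69e-06, adjusted p = 0.63 with an estimated correlation). With the cartilage score as a covariate 52 genes changed, and the matrix list gave a camera adjusted p = 4.09e-07. Cartilage scores did not overlap between CGDdt (1.13 to 2.41) and CGDndt (-0.24 to 0.48), so that fit cannot separate cartilage from the group here either. Ribosomal proteins were higher, and rps12 (1.65-fold), rpl37 (1.62-fold) and rps29 (1.60-fold) passed among 46. Adjusted over the list alone 22 were higher and 1 lower (median 0.54, camera adjusted p = 9.12e-10, adjusted p = 0.63 with an estimated correlation). Cell cycle genes (0 of 21 passing, 1 higher adjusted over the list alone, median 0.44, camera adjusted p = 0.0121) and endothelial and pillar cell markers (1 of 21, clec14a, 2.24-fold higher, and 2 higher adjusted over the list alone, median 0.37, adjusted p = 0.0119) were higher too, each with an adjusted p = 0.63 with an estimated correlation. The cell cycle list missed without CGDdt pool 3 (0.284) or CGDndt pool 1 (0.345), and the endothelial list without CGDdt pool 2 (0.103) or CGDndt pool 1 (0.118).

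Ionocyte genes were lower in damaged than in undamaged tissue, with cftr as the 1 of 21 members past the threshold, also adjusted over the list alone (median -0.50, camera adjusted p = 0.0119, adjusted p = 0.63 with an estimated correlation, 0.0666 without CGDndt pool 1). Skeletal muscle markers were lower as a group with 0 of 11 members passing, also adjusted over the list alone (median -1.88, camera adjusted p = 0.0121, adjusted p = 0.63 with an estimated correlation, 0.151 without CGDndt pool 2). Among epithelial junction and keratin genes krt18a.1 (2.38-fold), krt18b (2.01-fold) and cldn5 (2.27-fold), a claudin that endothelium also expresses, were higher and oclnb 2.2-fold lower, or 4 higher and 5 lower adjusted over the list alone (list adjusted p = 0.488). Among stress and metabolic genes, pfkfb3, a regulator of glycolysis, was 3.93-fold and xbp1, a factor of the unfolded protein response, 1.86-fold higher, while epas1 (2.01-fold) and cyp1b1 (3.32-fold) were lower. The lists that hold these 4 genes did not pass, with camera adjusted p-values of 0.220 for hypoxia and glycolysis, 0.220 for heat shock and 0.488 for antioxidant genes. The remaining lists lay between 0.263 for erythroid markers and 0.765 for oxidative phosphorylation. In these, 1 of 6 acute phase and antimicrobial genes and 1 of 4 thrombocyte markers were higher, also adjusted over the list alone. By the latter adjustment 1 apoptosis gene was higher and 1 neuronal or neuroepithelial marker lower too.

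**Figure D2:**
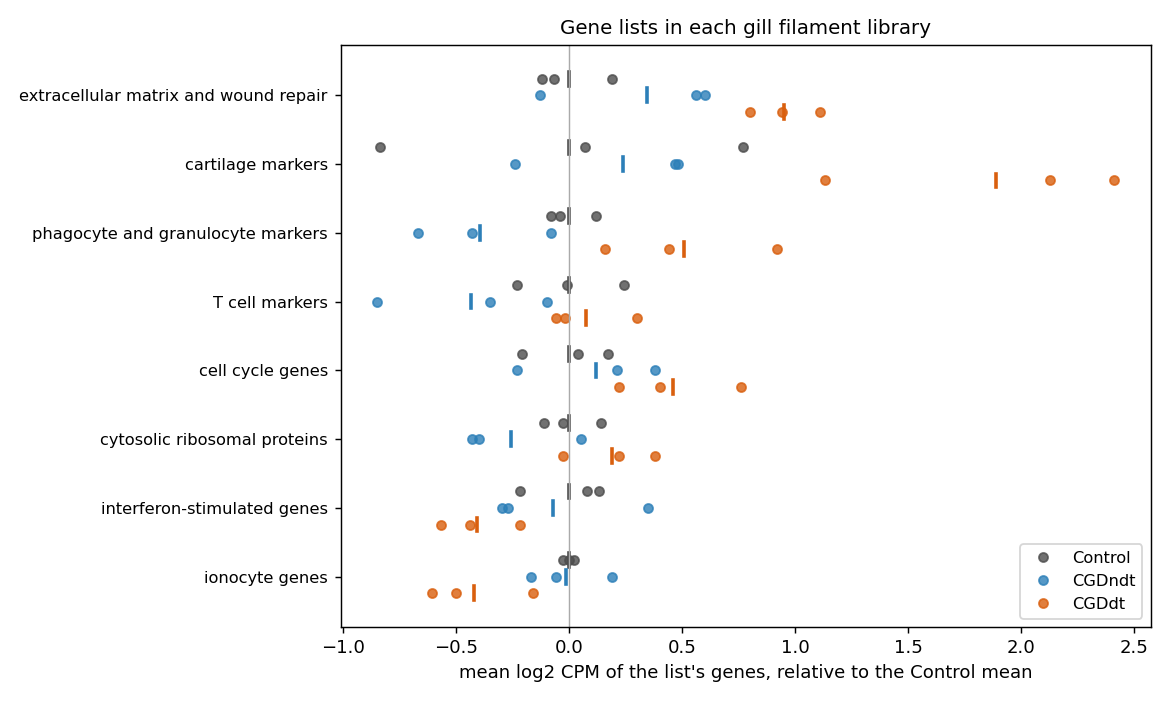
Mean log2 CPM of the genes of 8 lists in each of the 9 libraries, relative to the mean of the Control libraries, with a point for each library and a bar for the mean of the 3 libraries of a group. In CGDdt the matrix and wound repair list lay at 0.80 to 1.11, above all other libraries, and the cartilage list at 1.13 to 2.41.

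Comparisons that share a group also share its chance values, so overlaps were set against simulated unchanged groups. CGDdt against Control and CGDdt against CGDndt had 98 higher and 83 lower genes in common and 0 in opposite directions. Independent lists would share 4.22 and 2.03 genes, and the highest of 20 simulations shared 0. Neither value tests the size of the overlap. Unchanged groups leave few calls to share, and independent lists ignore that both comparisons use the same CGDdt libraries. The total of 181 was 45 without CGDdt pool 2, 41 without CGDdt pool 3, 92 without CGDndt pool 1, 49 without Control pool 2 and 40 without Control pool 3. Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.74 against a simulated mean of 0.50, with a covariance of 0.325 against 0.0824, a difference of 0.243. For CGDdt and CGDndt, each against Control, 5nt1a and nnt were the 2 shared calls. Over all genes r was 0.43 against a simulated mean of 0.50, and the covariance 0.140 against 0.0815, a difference of 0.0588. These rows had log2 fold changes of 13.36 and 12.95 (5nt1a) and -9.54 and -13.17 (nnt), which raise the covariance. The difference is thus not shown to be spread over many genes. Groups of 3 libraries are too small to be divided, so part of each overlap may come from the shared libraries.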

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

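The tests of explanations and the splits of the libraries were chosen after the results were seen.

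Some genes and lists moved in opposite directions in damaged and undamaged tissue, each compared with Control at an unadjusted p under 0.05, and differed between both tissues in the test of that difference. ccl19 had a log2 fold change of 2.02 in CGDdt and -0.94 in CGDndt (edgeR adjusted p of the difference 1.34e-05), sh2d1ab of 0.77 and -0.88 (0.00715) and cd22 of 0.94 and -0.67 (0.00824). In the reverse direction, cftr had log2 fold changes of -0.58 and 0.63 (0.0143) and grem1 of -1.62 and 1.47 (0.00909). The phagocyte and granulocyte list had medians of 0.22 and -0.31 (camera adjusted p of the difference 5.11e-05) and the ribosomal protein list of 0.22 and -0.22 (9.12e-10), each with an adjusted p of 0.63 with an estimated correlation. Of these genes ccl19 alone passed the adjusted threshold in CGDdt against Control, and 0 of the 5 passed in edgeR in CGDndt against Control, where 851 of all genes had an unadjusted p under 0.05, DESeq2 called 15 genes, ccl19 among them, and limma-voom called 2. Groups of 3 libraries are too small for a test of single outlying libraries.

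The T cell and phagocyte lists were lower in CGDndt than in Control, each with a median of -0.31 and a camera adjusted p of 0.81 with an estimated correlation. Without CGDndt pool 2, the CGDndt library with the lowest scores of both lists (-0.85 and -0.67 relative to the Control mean, on the log2 scale), each median was -0.26 and each camera adjusted p was 0.108. The medians thus moved little while both calls were lost, so an effect of this library alone and a lower leukocyte share in undamaged tissue cannot be told apart with 3 libraries per group. Between CGDdt and CGDndt both lists had a camera adjusted p of 0.63 with an estimated correlation and all libraries. With the preset correlation the difference of the phagocyte list passed without CGDndt pool 2 (0.00354), and that of the T cell list did not (0.102). That library also had the highest skeletal muscle score of all 9 (1.81), so another tissue composition of the piece may account for its low scores as well as fewer leukocytes in undamaged tissue, and neither was tested.

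The extracellular matrix list was higher in CGDdt than in Control, and whether more cartilage in the tissue pieces is the cause cannot be told. With the cartilage score as a covariate the list gave a camera adjusted p of 2.03e-12 and a median of 1.26 (quartiles 0.43 and 1.66) against 0.91 without it. In that fit, with 1 more term, 3 members passed singly against 13. Cartilage scores did not overlap between CGDdt (1.13 to 2.41) and Control (-0.84 to 0.77), so the fit cannot separate cartilage from the group. In CGDdt against CGDndt, which uses no Control column, the list passed too (camera adjusted p = 1.08e-05), with 8 members higher and 0 lower. Its adjusted p was 0.63 with an estimated correlation. Separate tabulation of the Control columns thus cannot account for that difference. Whether it added to the rise over Control (median 0.91, against 0.52 over CGDndt) cannot be told. A smaller share of epithelium would by itself raise other cell types. The cartilage (1.61) and endothelial (0.32) medians lay above 0, and the erythroid (-0.67), skeletal muscle (-1.24, 9 of 11 below 0) and thrombocyte (-0.23, with a mean of 0.55) medians below it. The epithelial list was not lower (0.21, 18 of 31 above 0). These values cannot settle that share. The erythroid median ranged from -0.92 to -0.24 as single libraries were left out, and muscle scores overlapped between CGDdt (-1.36 to -0.38) and Control (-0.53 to 1.06). A smaller share of epithelium, more cartilage and a change within the matrix-producing cells thus stay open. A camera adjusted p of 0.67 with an estimated correlation leaves the list call itself uncertain.

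The rows 5nt1a and nnt stood at or near 0 in opposite parts of the table. A candidate explanation is a single gene counted under different names in the Control columns and in the others. Its summed count passed in none of the 3 comparisons (edgeR adjusted p of 0.598, 0.796 and 0.218), and 0.194% of tested genes had a Control mean as close to the level of 5nt1a in the diseased libraries (171 CPM) as that of nnt (172 CPM). The Control columns also held the 5 blank rows, and these and nnt together spanned 196 rows. That span was taken with nnt included and the place of 5nt1a was not examined, so it does not test this explanation. A change of both genes with disease cannot be told apart from this, since group and part of the table coincide, although 0 other genes had at most 2 counts in each library of one part and at least 100 in each of the other.

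For 3 against 3 libraries there are 10 splits, which are too few for a share under 0.05. The real splits called 390, 2 and 352 genes in CGDdt against Control, CGDndt against Control and CGDdt against CGDndt, and the highest other splits 0, 6 and 0, so that 1, 3 and 1 splits, the real one included, gave as many. For lists the real splits called 9, 4 and 10 and the highest other splits 9, 8 and 8, and 4, 8 and 1 splits gave as many. The numbers of lists called in both comparisons with Control thus did not stand out from those of mixed splits.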

How the results depend on the processing

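Counts of genes stayed within 1.5 times the reported count under both other scalings (385 and 388 genes in CGDdt against Control, 344 and 386 in CGDdt against CGDndt, 2 in CGDndt against Control) and both other filters (434 and 381, 371 and 365, and 2), but without a filter 6 of the 9 lists passed in CGDdt against Control. No named gene or list past the threshold reversed its direction under any alternative run. DESeq2 gave 1073, 15 and 932 genes in CGDdt against Control, CGDndt against Control and CGDdt against CGDndt, 8 shared by the comparisons with Control and 498 changed in a single direction in both comparisons with CGDdt, against 390, 2, 352, 2 and 181 reported. In CGDdt against CGDndt, 48.1% of the DESeq2 calls were higher. limma-voom gave 986 and 190 genes in the comparisons of CGDdt with Control and CGDndt, and the 6 libraries alone, a fit with fewer libraries, gave 728 and 132. With an estimated correlation camera called 0, 0 and 0 lists against 9, 4 and 10. Chosen after seeing the data, the fit without 5nt1a and nnt gave 0 genes in CGDndt against Control (846 with an unadjusted p under 0.05) and 0 shared genes, because these rows were the calls. Also chosen after seeing the data, the pool number as a replicate block gave 209 and 181 genes for CGDdt against Control and CGDndt and 97 in both. Same-numbered libraries had r of -0.14 to 0.09, and differently numbered ones -0.18 to 0.23, the highest for CGDdt pool 3 and CGDndt pool 2. A pool number names no known fish, so these values cannot exclude pairing. Whether any libraries share fish is not known. Likewise chosen later, the cartilage score as a covariate gave 27 and 52 genes, 23 in both, and 6 lists in CGDdt against CGDndt, and 5 of the 9 lists in CGDdt against Control still passed. Leaving out each library in turn gave 50 to 593 genes and 6 to 10 lists in CGDdt against Control (fewest without Control pool 3, most without CGDndt pool 1), 2 to 4 genes and 3 to 7 lists in CGDndt against Control, 66 to 355 genes and 8 to 11 lists in CGDdt against CGDndt (fewest without CGDdt pool 2, most without CGDdt pool 1), 2 to 3 shared genes, and 40 to 215 genes changed in both comparisons with CGDdt. Apart from the removed rows, the cause was not tested. Of 320 results for named genes, 318 kept their side of the threshold with median-of-ratios scaling, 280 in DESeq2, where 39 more passed, 265 without CGDdt pool 3, where 54 no longer passed, and 251 with the cartilage score, the lowest number, where 60 no longer passed and 8 moved. A term for the 2 of 3 CGDndt samples whose titles carry another name series than the CGDdt samples was not run, because the columns match no single sample. CGDdt against CGDndt is thus partly confounded with the series. Both comparisons with Control are wholly confounded with it, since no diseased sample has the series of the Control samples. In simulated counts 41.0% to 46.9% of 2-fold changes were recovered, so depth and spread limit smaller changes.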

Other observations

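Genes named here were chosen after their values were seen, and so were the symbols of the ribosome assembly group. The test of that group's members that had not been called was chosen before its result was seen.

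Further genes passed in both comparisons of CGDdt, in edgeR's quasi-likelihood test, and in each of the 9 fits that left out a library. ccr2, a chemokine receptor of monocytes, was at 41.5 ± 14.2 CPM in CGDdt, 8.48 ± 1.12 in CGDndt and 9.38 ± 0.511 in Control (SD, n = 3), with an adjusted p of 0.0033 against Control and 0.0038 against CGDndt. The cholesterol-esterifying enzyme soat1 was at 90.5 ± 10 CPM against 22 ± 7.95 in Control (log2 fold change 2.04, adjusted p = 0.00438), and tgm2, a transglutaminase that cross-links matrix, at 733 ± 142 against 241 ± 63.6 (log2 fold change 1.60, adjusted p = 0.00904). The zinc transporter slc30a8 had log2 fold changes of 2.79 and 2.85 and the transcription factor glis3 of 3.00 and 2.48 against Control and CGDndt. Lower in both were ptpn22, a phosphatase of lymphocyte signalling (log2 fold changes -1.20 and -1.25), and sptlc3, an enzyme of sphingolipid synthesis (-1.28 and -1.07).

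A group of ribosome assembly genes was gathered after the rises were seen, so its tests on the same libraries are no independent evidence. Of 94 tested members 13 were higher in CGDdt than in Control, among them polr1a, the largest subunit of RNA polymerase I, with a log2 fold change of 1.00 (edgeR adjusted p = 0.00838), bop1 with 1.12 (0.0156) and nhp2 with 1.27 (0.0318). Of the 81 other members 73 lay above 0, with a median of 0.61 (camera p = 2.03e-13), and p was 0.078 with an estimated correlation. The mean log2 CPM of the group lay 0.43 to 0.76 above the Control mean in the CGDdt libraries and between -0.09 and 0.37 in the CGDndt libraries. The group was also higher in CGDdt than in CGDndt (88 of 94 above 0, camera p = 1.84e-11, 0.13 with an estimated correlation) and in CGDndt than in Control (66 of 94 above 0, median 0.21, p = 0.000262, 0.38 with an estimated correlation, and 0.238 without CGDndt pool 2). Ribosomal proteins went the other way in CGDndt against Control (31 of 46 below 0, median -0.22). A rise of the group as a set cannot be told apart from genes that vary together between few libraries.

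DESeq2 called 15 genes in CGDndt against Control, of which edgeR called 2, 5nt1a and nnt. In simulated counts of this comparison DESeq2 called 28 unchanged genes and edgeR 7, so calls of DESeq2 alone are weak. Among the other 13 were cd28 (log2 fold change -1.61, DESeq2 adjusted p = 0.00626), tmsb1, a thymosin (-1, 0.00746), ccl19 (-0.93, 0.0309), hoxd3a (3.14, 0.0309) and hoxd4ab (4.11, 0.0324). The Hox genes differed widely between libraries of a group. hoxd3a was at 1.37, 13.4 and 25.6 CPM in the CGDndt libraries of pools 1 to 3, at 18.6, 7.01 and 20.8 CPM in CGDdt and at 2.31, 0.621 and 1.68 CPM in Control. The titin gene ttn.1, a skeletal muscle marker, was at 15.1, 381 and 136 CPM in CGDndt, at 20.7, 7.57 and 8.91 CPM in CGDdt and at 24.4, 21.1 and 212 CPM in Control.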
